A study of Mus musculus with 6 samples.

How the data were processed

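The series measured gene expression in single cells of mouse lung, in 3 Control libraries and 3 libraries of lungs infiltrated by acute myeloid leukaemia (AML). Per the labels' protocols, lungs were digested with Liberase and DNaseI, niche cells were sorted, sorted GFP-positive leukaemia cells were added to the AML libraries at 20% with 80% niche cells, and libraries were made with the 10x Chromium Single Cell 3' v3.1 kit. The deposited counts are raw UMI counts per gene and cell barcode over 32285 features, made by the authors with Cell Ranger on mm10. The file headers name version 6.0.1 of that program and the submitters' processing notes version 7.0.0, so the version is open. No annotation of cells by the authors was used here; cell classes were rebuilt, and a difference from the classes of the study may come from that. Coordinates are those of the mm10 build in GENCODE M21.

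The lists of genes, the markers of cell classes, the filters other than that of doublets, the main tests, the rule for named genes and most alternatives were chosen before the data were examined. The doublet rule was set after the automatic Scrublet threshold had called few Control cells. That threshold as an alternative and the leaving out of clusters mostly of 1 library were added afterwards. So were tests in the closing section: those of free RNA sources, of lymphocytes, of dissociation, and of UMIs per cell beyond the type I interferon list in general capillary cells. The tests there of a heat shock programme and of UMIs per cell for that list were written before they were run, for patterns already seen.

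Of 28516 barcodes, 24640 were kept: 3415 had fewer than 500 genes and 461 others had more than 15% mitochondrial UMIs. Doublets were scored with Scrublet in each library and the top-scoring cells removed, as many as 0.8% per 1000 cells, which took 895 cells (3.63%) and left 23745. The automatic threshold of Scrublet called 21 of 9075 Control cells (0.231%), too few to serve, and 201 cells in all. UMIs were scaled to 10000 per cell and logged, 2000 variable genes and 30 principal components were taken, and cells with 15 nearest neighbours were clustered by Leiden at resolution 1.0 (scanpy 1.11.5, igraph 0.11.9, Python 3.11.15, seed 7). A cluster took the name of the class whose fixed markers led it when at least 3 of them were detected. It stayed unnamed when its top 10 genes held markers of a class of another lineage, as many as its own or more. The same held when another class of its lineage had more markers there, or when it had few UMIs and none of its markers there. A class name means like that cell type by these markers. Of 34 clusters 4 stayed unnamed. Between Control and AML libraries no class was tested unless each library held at least 20 of its cells, which left 9 classes. General capillary, alveolar type 2 and aerocyte classes hold several clusters and the others 1 each. The clusters that hold such a class in each group are named beside its result.

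UMIs were summed per library and class, since cells are not replicates. Sums were tested with edgeR 4.0.16 (quasi-likelihood with robust fit, TMM scaling, filterByExpr; R 4.3.3), AML minus Control, with Benjamini-Hochberg adjustment over the genes of the class at a threshold of 0.05. An adjusted p given without another tool is from this test. CPM values are UMIs scaled to a library total after TMM scaling, given as mean and SD of 3 libraries. The median log2 change of all tested genes lay between -0.009 and 0.014 over the classes. On simulated data with 200 changed genes, 81 to 99% of 4-fold changes and 26 to 64% of 2-fold changes were called per class, with 0.8 to 6.5% false calls. Each class was simulated once, with genes drawn independently at 1 common dispersion (0.0279 to 0.0518 over the classes). No effect shared by the genes of a library was simulated, so these rates may not carry over to the real libraries.

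The 26 gene lists were type I interferon response, interferon gamma induced, MHC class I and class II presentation, NF-kB inflammatory, leukocyte adhesion, acute phase and STAT3 response, complement, haematopoietic support factors, hypoxia response, mitochondrial respiratory chain, fibrillar matrix, basement membrane, TGF-beta response, angiogenesis and tip cell, Notch pathway, proliferation, p53 targets, unfolded protein response, glucocorticoid response, lipid handling, dissociation stress, and markers of myeloid, lymphoid, erythroid or platelet, and epithelial cells. A list with at least 5 measured members was tested in a class with camera in limma 3.58.1, with the preset correlation of 0.01, adjusted over all 174 pairs. Beside it stand camera with an estimated correlation, the members past the threshold over all genes, and those adjusted over the list alone. The lymphoid list had too few measured members for a test in any class.

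Named genes follow a fixed rule. In each class they are the genes past the threshold with no overlap between AML and Control libraries and a mean log2 CPM of at least 4 that changed most, 10 per direction in the 4 largest classes and 4 in the others. Up to 4 members with the smallest p were added from each list that was called or had at least 3 members past the threshold. Left out of the first part were predicted genes, ribosomal, mitochondrial and Y-linked genes, Xist, antigen receptor segments, and genes higher in the haematopoietic cells of the AML libraries than in the class. Haemoglobin and Cd74 in general capillary cells and single members that passed in small counts were named after their values were seen.

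Shares of a class are percent of the non-haematopoietic cells of named clusters per library, compared by an exact two-sided permutation test over 20 permutations, whose smallest p is 0.1, with Benjamini-Hochberg adjustment over 14 classes. The plan named all non-haematopoietic cells as the base, and the unnamed clusters were left out of it; shares with them in the base were added after the data were seen. Shares of haematopoietic cells have exact Clopper-Pearson intervals at 95%, and a count of 0 allows up to the upper bound. The difference of the AML effect between the classes with the most cells in their smallest library was tested with limma on differences of log2 CPM (prior count 2) within each library, with the 5 genes of smallest p per direction taken as named.

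Alternatives were DESeq2 size factors, DESeq2 1.42.0, no low-count filter, the replicate number as a block, each library left out in turn (not run for DESeq2), a stricter cell filter (1000 genes, 10% mitochondrial UMIs), called doublets kept, Leiden resolution 0.5, subtraction of free RNA, equal cells per library, fry, lists without members higher in haematopoietic cells, a prior count of 0.5, and the automatic Scrublet threshold and clusters mostly of 1 library left out. Free RNA subtracted here is that of each library's own haematopoietic cells, scaled by their marker genes, and of no other cell type. All 10 splits of the libraries into 3 and 3 were fitted too. Haematopoietic classes were left out of the comparisons because cells had been added to 1 group. Other tools were scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.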

Results

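Single-cell RNA sequencing measured the transcripts of lung niche cells, the non-haematopoietic cells of the tissue, in 3 libraries from normal mouse lungs (Control 1, 2 and 3) and 3 libraries from mouse lungs infiltrated by acute myeloid leukaemia with altered Trp53 (AML 1, 2 and 3). Per the labels' protocols, the lungs were digested with enzymes, niche cells were sorted, and sorted GFP-positive leukaemia cells made up 20% of the suspension in the AML libraries. The deposited counts held 28516 cell barcodes and 19060359, 26789176 and 22687245 unique molecular identifiers (UMIs) in Control 1, 2 and 3, against 39919902, 45953347 and 46018541 in AML 1, 2 and 3. After the filters, 1718, 3673 and 3444 cells of the Controls and 4496, 4624 and 5790 cells of the AML libraries were used. Their median UMIs per cell were 8323.5, 5504 and 4794.5 in the Controls and 4298, 4685.5 and 3723 in the AML libraries. In general capillary endothelial cells, the largest class, all pairs of libraries differed by more than counting noise, with a chi-square per degree of freedom of 8.56 to 99.4. No library was thus a copy of another, but separate preparations of the same animal would differ too. Each library was counted as a sample of its own. The labels do not say that the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. The labels name no sequencing batch or date, so no value within a batch could be given.

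The comparison asks how the niche cells of the lung differ when leukaemia cells occupy it. Cells fell into 34 clusters, 30 of which took a name from markers chosen before the data were examined. Class names below stand for clusters that are like that cell type by those markers. Haematopoietic clusters made up 3.39% ± 1.08 of the cells in the Controls and 22.7% ± 4.62 in the AML libraries (SD, n = 3 each). Clusters found almost only in AML libraries held 13.4% of AML 1 (604 of 4496 cells, exact 95% binomial interval 12.45 to 14.5%), 24.5% of AML 2 (23.3 to 25.8%) and 18.9% of AML 3 (17.9 to 19.9%), beside the 20% of leukaemia cells that the labels state. In Control 1 they held 0 of 1718 cells, which allows a share of up to 0.21%. These intervals cover counting error only. The cells of these clusters carried Hba-a1, a haemoglobin chain, at 903 ± 204 CPM (UMIs of a gene scaled to a common total) and Gata2, a transcription factor of early blood cells, at 41.8 ± 12.3 CPM, with 0 CPM of the granule genes Mpo and Elane. Because the share of haematopoietic cells was set by mixing, haematopoietic classes entered no comparison between the groups in this part. Unnamed clusters held 8.52% ± 8.79 of Control cells (2.5%, 4.44% and 18.61% of Control 1, 2 and 3) and 1.27% ± 0.09 of AML cells and entered no class.

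**Figure D1:**
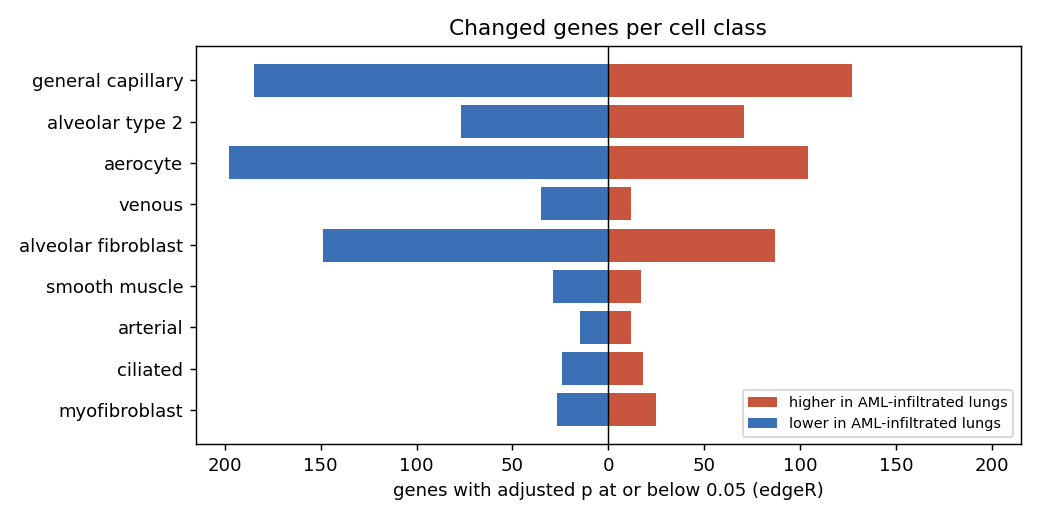
Genes that changed between 3 AML and 3 Control libraries in each of 9 cell classes, as bars of the number of genes (horizontal axis) at an edgeR adjusted p at or below 0.05, higher in AML-infiltrated lungs to the right and lower to the left. General capillary endothelial cells had 127 higher and 185 lower genes, and aerocytes 104 higher and 198 lower genes.

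General capillary endothelial cells, which line the exchange capillaries and were the most numerous class, had lower Hspa1a and Ifi44 in AML-infiltrated lungs, and higher Lrg1, Ly6c1 and Timp3. Lrg1, a secreted glycoprotein of the acute phase (ENSMUSG00000037095, chromosome 17, 56119678 to 56122001, mm10), rose 6.97-fold, from 60.6 ± 41.3 to 424 ± 181 CPM (SD, n = 3 each; log2 change 2.80 ± 0.52 SE, edgeR adjusted p = 0.0361). Ly6c1, a surface antigen of small vessels, rose 4.64-fold from 1438 ± 740.0 to 6669 ± 1588 CPM, and Timp3, an inhibitor of matrix proteases, rose 4.62-fold. Cirbp, a cold-inducible RNA-binding protein, rose 3.76-fold and the imprinted zinc finger gene Peg3 rose 5.13-fold. Among falling genes, Hspa1a, the inducible HSP70 chaperone (chromosome 17, 34969190 to 34972156), went from 64.6 ± 26.2 to 11.2 ± 2.32 CPM (log2 change -2.53 ± 0.31 SE, edgeR adjusted p = 0.0165). The interferon-induced gene Ifi44 fell 4.78-fold and the interferon-induced GTPase gene Iigp1 fell 3.66-fold. Esm1, a secreted proteoglycan of endothelial tip cells, fell 3.42-fold, Ltbp4, which binds latent TGF-beta, fell 3.96-fold, and the chemokine receptor gene Cxcr4 fell 7.75-fold from a low level of 16.3 ± 4.47 CPM. Of Notch ligands, Dll4 fell 2.52-fold and Dll1 rose 2.01-fold; the lymphangiogenic growth factor gene Vegfc rose 2.18-fold and Bmp4 fell 2.09-fold.

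Of 11585 genes tested in general capillary cells, 312 passed (127 higher, 185 lower; 2703 at an unadjusted p below 0.05). In all 312 (100%), the 3 AML values lay apart from the 3 Control values, as they did in 31.1% of the tested genes against 10% by chance. Genes that pass this test with 3 libraries per group are nearly sure to lie apart. Their share is therefore no separate support, here or in the other classes. A further limit on naming was that 34 of the 186 passing genes that met the rule for level and separation were higher in haematopoietic cells, among them Ldha and Hsph1. The count was 0 without Control 1 (edgeR, 2076 at an unadjusted p below 0.05), 134 without Control 2, 18 without Control 3, 1289 without AML 1, 107 without AML 2 and 3 without AML 3. In that order, 0, 25, 9, 42, 23 and 2 of the 42 named genes that passed still did. Lrg1 was lost without Control 1, Control 3, AML 2 or AML 3 (edgeR adjusted p = 0.166, 0.12, 0.0652 and 0.136). Without the low-count filter Lrg1, Iigp1 and Bhlhe40 were lost (edgeR adjusted p = 0.134, 0.111 and 0.118), with equal cells per library Esm1 and Bmp4 (0.0536 and 0.0868), with the replicate block Isg15 (0.0562) and with free RNA subtracted Hmgb2 (0.0532). Changed genes numbered 881 with DESeq2 and 845 without the low-count filter. Cluster 0 held 52.5% of the AML cells and 0.3% of the Control cells of this class, while clusters 1, 3 and 6 held 39.0%, 27.7% and 18.1% of its Control cells and 21.9%, 0.5% and 2.4% of its AML cells. These percents pool libraries that differed. Cluster 0 held 271 of 2411 cells of AML 1, 1716 of 2132 of AML 2 and 1863 of 2787 of AML 3. Cluster 1 held 1460 of the AML 1 cells. Cluster 3 held 613 of 892 cells of Control 1, against 322 of 2165 in Control 2. Ly6c1 was the top gene of cluster 0 and Esm1 that of cluster 6. For these genes a shift in the mix of clusters cannot be told apart from a change within cells. For the other genes and the lists of this class it was not tested. Median UMIs per cell of the class were 4950 in the Controls and 3349.5 in the AML libraries.

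**Figure D2:**
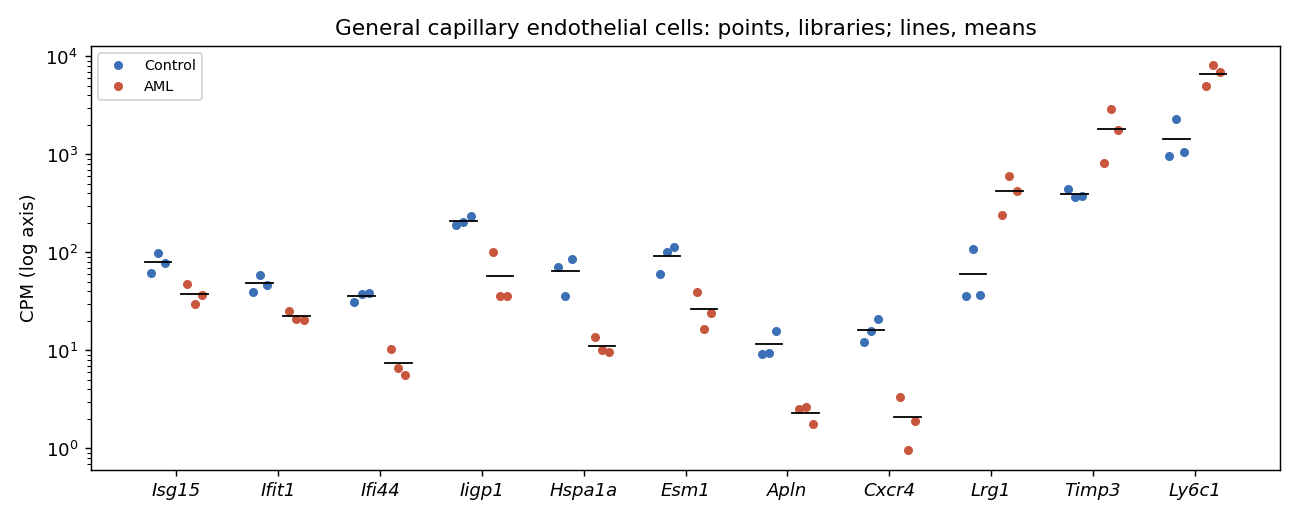
CPM (log axis) of 11 genes in general capillary endothelial cells of each library, with Controls in blue, AML libraries in red and a line at each group's mean. Ifi44 falls from 36.0 to 7.49 CPM and Lrg1 rises from 60.6 to 424 CPM between the group means, with no overlap of single libraries.

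By fixed lists, type I interferon response genes were lower in general capillary cells. All 23 measured members had a log2 change below 0 (median -1.07), 7 fell, and 19 fell when adjusted over the list alone (camera adjusted p = 3.65e-12; adjusted p = 0.425 with an estimated correlation). Ifit1 fell 2.17-fold and Isg15 fell 2.08-fold. Of 20 interferon gamma induced genes, 2 fell (Iigp1 and Tgtp1), while adjusted over the list alone 12 fell and 2 rose (camera adjusted p = 3.89e-08; adjusted p = 0.446 with an estimated correlation). Of 19 genes of MHC class I presentation, Nlrc5, which activates the class I genes, fell 3.13-fold. In this list, 6 fell adjusted over the list alone (camera adjusted p = 3.92e-06; adjusted p = 0.517 with an estimated correlation). None of 7 MHC class II genes passed (edgeR, 0 over all genes or adjusted over the list alone, 0 at an unadjusted p below 0.05, 0 with DESeq2), with a list median of -0.75 (camera adjusted p = 0.00402; adjusted p = 0.522 with an estimated correlation). Cd74, the invariant chain, stood at 361, 541 and 431 CPM in Control 1, 2 and 3 and at 619, 93.7 and 64.8 CPM in AML 1, 2 and 3. Of 18 genes of angiogenesis and tip cells, 5 fell, including Apln, the ligand of the apelin receptor, at 4.97-fold. In this list, 9 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000441; adjusted p = 0.425 with an estimated correlation).

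Among lists that rose in general capillary cells, the hypoxia response had 21 measured genes, of which Ldha and Bhlhe40 rose. In this list, 11 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000324; adjusted p = 0.425 with an estimated correlation). Of 15 acute phase and STAT3 genes, Lrg1 and Bcl3 rose. In this list, 3 rose adjusted over the list alone (camera adjusted p = 0.0025; adjusted p = 0.517 with an estimated correlation). Of 18 proliferation genes, Top2a and Hmgb2 rose. In this list, 4 rose adjusted over the list alone (camera adjusted p = 0.00177; adjusted p = 0.425 with an estimated correlation); all 18 were higher in the haematopoietic cells of the AML libraries than in the class. The myeloid marker list, 6 genes measured, was also higher (camera adjusted p = 0.0301; adjusted p = 0.425 with an estimated correlation), with 0 members past edgeR (3 at an unadjusted p below 0.05, 0 with DESeq2), and lost its call without Control 1 (adjusted p = 0.139) or AML 1 (adjusted p = 0.0724). The 23 genes of the mitochondrial respiratory chain had a median of 0.30 with 22 above 0 and 0 past edgeR (7 at an unadjusted p below 0.05, 0 with DESeq2; camera adjusted p = 9.89e-05; adjusted p = 0.535 with an estimated correlation), and 21 of them were higher in haematopoietic cells. The erythroid and platelet marker list was lower: of 5 measured genes Pf4 fell, and all 5 fell adjusted over the list alone (camera adjusted p = 0.00804; adjusted p = 0.517 with an estimated correlation). Haemoglobin Hbb-bs stood at 30.1, 22.2 and 1224 CPM in Control 1, 2 and 3 of this class and at 2.9, 0.6 and 0.6 CPM in AML 1, 2 and 3.

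Alveolar type 2 epithelial cells, which make surfactant, had lower genes of MHC class II presentation in AML-infiltrated lungs, and higher Spink5 and Angptl4. Of 7 MHC class II genes, 3 fell, and all 7 fell adjusted over the list alone (camera adjusted p = 6.17e-07; adjusted p = 0.425 with an estimated correlation). Ciita, the master regulator of class II genes, fell 4.97-fold, H2-Ab1 fell 2.61-fold, and Cd74 (chromosome 18, 60803848 to 60812652) fell from 3119 ± 860.2 to 1333 ± 353 CPM (SD, n = 3 each; log2 change -1.23 ± 0.29 SE, edgeR adjusted p = 0.0491). Spink5, a serine protease inhibitor, rose 4.86-fold from 35.7 ± 16.7 to 175 ± 40.6 CPM (log2 change 2.28 ± 0.34 SE, edgeR adjusted p = 0.0267). The paraoxonase gene Pon1 rose 4.10-fold, the cytochrome P450 gene Cyp2b10 rose 3.19-fold, the glutathione transferase gene Gsta3 rose 3.01-fold and Angptl4, an inhibitor of lipoprotein lipase, rose 3.70-fold. The calcium channel gene Trpv6 rose 2.69-fold and Cirbp rose 3.81-fold. Among falling genes, Hspa1a fell 5.53-fold, the collagen chaperone gene Serpinh1 fell 4.04-fold, Igfbp7 fell 3.80-fold and the laminin gene Lama3 fell 4.25-fold. Of 15 glucocorticoid response genes, Hif3a rose and Tsc22d3 fell. In this list, 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0171; adjusted p = 0.433 with an estimated correlation; 0.0625 without AML 2).

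In all, 148 of 10013 genes passed in alveolar type 2 cells (71 higher, 77 lower; 1918 at an unadjusted p below 0.05), all 148 with AML and Control values apart, against 26.0% of the tested genes and 10% by chance. Markers of endothelial cells summed to 285 ± 315 CPM in the Controls and 56.9 ± 23.8 CPM in the AML libraries of this class, with 648 CPM in Control 1, and markers of mesenchymal cells to 19.9 ± 19.9 and 2.9 ± 1.2 CPM, with 42.7 CPM in Control 1. The angiogenesis list, 6 genes measured and Nrp1 lower at 2.74-fold, moved the same way (camera adjusted p = 0.00177; adjusted p = 0.484 with an estimated correlation). So did leukocyte adhesion, with 0 of 9 genes past edgeR (2 at an unadjusted p below 0.05, 2 with DESeq2; camera adjusted p = 0.0259; adjusted p = 0.425 with an estimated correlation), a call lost without AML 1 (adjusted p = 0.103). The epithelial marker list was higher, with 0 of 8 genes past edgeR (2 at an unadjusted p below 0.05, 2 with DESeq2; camera adjusted p = 0.0463; adjusted p = 0.611 with an estimated correlation); its adjusted p was 0.139 without Control 1, 0.0552 without Control 3, 0.0877 without AML 1, 0.0846 without AML 2 and 0.068 without AML 3. The count of changed genes was 223 without Control 2, 48 without Control 3, 267 without AML 1, 5 without AML 2 and 0 without AML 3 (edgeR, 1290 at an unadjusted p below 0.05). Without Control 1, 2 and 3 and AML 1, 2 and 3 in turn, 19, 24, 15, 29, 3 and 0 of the 30 named genes that passed still did. Cd74 was lost without Control 2, Control 3, AML 2 or AML 3 (edgeR adjusted p = 0.0752, 0.155, 0.322 and 0.287), Ciita without AML 2 or AML 3 (0.0811 and 0.119) and Spink5 without Control 1, AML 2 or AML 3 (0.133, 0.162 and 0.139). Cd74 was also lost with DESeq2 size factors, the automatic Scrublet threshold or free RNA subtracted (edgeR adjusted p = 0.056, 0.056 and 0.0563), and H2-Ab1 with the replicate block, the automatic threshold or free RNA subtracted (0.0797, 0.056 and 0.0563). With doublets kept or the automatic threshold, Pon1 (edgeR adjusted p = 0.0693 and 0.0643), Cyp2b10 (0.0623 and 0.056) and Igfbp7 (0.0946 and 0.0628) were lost, and with the automatic threshold Cirbp (0.0628). Nrp1 was lost with the automatic threshold or free RNA subtracted (edgeR adjusted p = 0.0627 and 0.0586). The count was 266 with DESeq2, 794 without the low-count filter, 460 at the lower clustering resolution, 80 with the automatic Scrublet threshold and 454 without clusters mostly of 1 library. Cluster 21 held 31.7% of the Control cells and 0.8% of the AML cells of this class, and cluster 4 the other cells. Of the 218 cells of cluster 21, 209 came from Control 1, 1 from Control 2 and 2 from Control 3. It was thus mostly of 1 library and no trait of all Controls. Control 1 had 322 cells in this class. Median UMIs per cell were 1699.5 in cluster 21 and 14321 in cluster 4.

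Aerocytes, the large capillary cells specialised for gas exchange, had lower Mmp15, Tbxa2r and Col12a1 in AML-infiltrated lungs, and higher Timp3 and Ly6c1. Mmp15, a membrane-bound matrix protease (ENSMUSG00000031790, chromosome 8, 95352268 to 95375080), fell from 38.9 ± 13.4 to 2.32 ± 1.45 CPM (SD, n = 3 each; log2 change -4.02 ± 0.46 SE, edgeR adjusted p = 0.000322). Timp3 rose 3.76-fold, from 1341 ± 169 to 5049 ± 1075 CPM (log2 change 1.91 ± 0.22 SE, edgeR adjusted p = 0.000322), and Ly6c1 rose 3.52-fold. The thromboxane receptor gene Tbxa2r fell 6.27-fold, the collagen gene Col12a1 fell 5.29-fold, the sodium channel subunit gene Scn3b fell 4.48-fold and the matrix gene Abi3bp fell 4.10-fold; markers of mesenchymal cells summed to 15.4 ± 2.4 CPM in the Controls and 4.8 ± 1.3 CPM in the AML libraries of this class. The mitochondrial carrier gene Ucp2 rose 4.59-fold, the guanine deaminase gene Gda rose 7.79-fold and the haem oxygenase gene Hmox1 rose 4.86-fold. Serpina3m, a serine protease inhibitor gene, went from 0.574 ± 0.994 to 63.4 ± 57.2 CPM. Hspa1a fell 19.5-fold, from 182 ± 87.1 to 9.31 ± 3.62 CPM. Of 14 genes of angiogenesis and tip cells, 4 fell. In this list, 7 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000133; adjusted p = 0.425 with an estimated correlation). Apln fell 4.56-fold and Kdr, the main VEGF receptor, fell 2.08-fold from 2215 ± 179 CPM, both also naming markers of this class, and Nrp1, a VEGF coreceptor, fell 2.74-fold.

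In aerocytes, 4 of 15 interferon gamma induced genes fell, among them the guanylate-binding protein genes Gbp4 at 3.31-fold and Gbp7 at 2.94-fold. In this list, 7 fell adjusted over the list alone (camera adjusted p = 2.37e-06; adjusted p = 0.425 with an estimated correlation). Of 12 acute phase and STAT3 genes, Bcl3 and Cebpd rose. In this list, 7 rose adjusted over the list alone (camera adjusted p = 2.04e-06; adjusted p = 0.433 with an estimated correlation). Of 18 hypoxia genes, Ankrd37 and P4ha2 rose and P4ha1 fell. In this list, 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00225; adjusted p = 0.425 with an estimated correlation). Of 7 NF-kB inflammatory genes, Birc3, an inhibitor of apoptosis, rose 3.25-fold. In this list, 2 rose adjusted over the list alone (camera adjusted p = 0.0238; adjusted p = 0.457 with an estimated correlation), a call lost without members higher in haematopoietic cells (adjusted p = 0.139). Across aerocytes 302 of 8991 genes passed (104 higher, 198 lower; 1417 at an unadjusted p below 0.05), all with AML and Control values apart, against 22.8% of the tested genes and 10% by chance. The count was 68 without AML 2, 74 without AML 3 and 602 without the low-count filter, and 29, 36, 34, 37, 25 and 26 of the 40 named genes that passed still did without Control 1, 2 and 3 and AML 1, 2 and 3 in turn. Serpina3m and Ankrd37 were lost without each Control (edgeR adjusted p = 0.212, 0.272 and 0.267 for Serpina3m and 0.237, 0.199 and 0.265 for Ankrd37 without Control 1, 2 and 3), and Serpina3m also without AML 3 (0.0954). Hmox1 was lost without Control 1 and 3 and AML 2 and 3 (edgeR adjusted p = 0.1, 0.0623, 0.117 and 0.0978). Gda, Ucp2, Apln and Hspa1a were lost without Control 1 (edgeR adjusted p = 0.116, 0.144, 0.154 and 0.0648). With doublets kept Birc3, Ankrd37 and Cebpd were lost (edgeR adjusted p = 0.0659, 0.0714 and 0.0552), with the automatic Scrublet threshold Birc3 and Ankrd37 (0.0562 and 0.076), and with equal cells per library P4ha1, P4ha2 and Serpina3m (0.0703, 0.0584 and 0.152). Serpina3m was also lost without the low-count filter, with the stricter cell filter and at the lower clustering resolution (edgeR adjusted p = 0.118, 0.0523 and 0.0579). Cluster 11 held 72.5% of the Control cells and 7.3% of the AML cells of this class, and cluster 9 the reverse, 27.5% and 92.7%. Kdr and Apln were among the top genes of cluster 11, and Ly6c1 among those of cluster 9. For these genes too, a shift in the mix of clusters cannot be told apart from a change within cells. For the other genes and the lists of aerocytes it was not tested.

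Venous endothelial cells had lower Ifi44, Gbp3 and Gbp4 in AML-infiltrated lungs, and higher Tiparp and Ly6c1. Ifi44 (chromosome 3, 151730922 to 151749960) fell from 44.1 ± 8.76 to 7.49 ± 5.62 CPM (SD, n = 3 each; log2 change -2.42 ± 0.39 SE, edgeR adjusted p = 0.0234), and the interferon-induced GTPase genes Gbp3, Gbp4 and Tgtp2 fell 4.05-fold, 4.01-fold and 3.80-fold. Tiparp, a target of the aryl hydrocarbon receptor, rose 4.43-fold, the taurine transporter gene Slc6a6 rose 3.73-fold, the adrenomedullin coreceptor gene Ramp3 rose 3.52-fold and Ly6c1 rose 3.36-fold. Mmp15 fell 4.998-fold, Hspa1a fell 4.69-fold and the collagen gene Col14a1 fell 3.58-fold; markers of mesenchymal cells summed to 432 ± 27.4 CPM in the Controls and 220.0 ± 36.1 CPM in the AML libraries of this class. Of 15 interferon gamma induced genes, 5 fell. In this list, 9 fell adjusted over the list alone (camera adjusted p = 6.38e-11; adjusted p = 0.425 with an estimated correlation). Of 20 type I interferon genes, Ifi44 and Stat2 fell. In this list, 6 fell adjusted over the list alone (camera adjusted p = 3.05e-09; adjusted p = 0.425 with an estimated correlation). Among venous cells of 2000 to 6000 UMIs, 7 in the smallest library, the median log2 difference of this list was 0.425, against -0.817 over all cells of the class. Of 19 MHC class I genes, 0 passed edgeR (5 at an unadjusted p below 0.05, 0 with DESeq2). In this list, 3 fell adjusted over the list alone (camera adjusted p = 4.6e-08; adjusted p = 0.476 with an estimated correlation). Of 15 p53 target genes, 0 passed edgeR (3 at an unadjusted p below 0.05, 1 with DESeq2). In this list, 1 rose adjusted over the list alone (camera adjusted p = 0.0364; adjusted p = 0.425 with an estimated correlation); this call was lost without Control 1, Control 3, AML 2 or AML 3 (adjusted p = 0.0565, 0.0922, 0.186 and 0.111). In this class 47 of 8642 genes passed (12 higher, 35 lower; 1019 at an unadjusted p below 0.05), all with AML and Control values apart, against 18.8% of the tested genes and 10% by chance. The count was 0 without Control 1 (edgeR, 746 at an unadjusted p below 0.05), 20 without Control 2, 0 without Control 3 (842), 322 without AML 1 and 0 without AML 3 (730), with 0, 10, 0, 28, 21 and 0 of the 28 named genes that passed still passing without Control 1, 2 and 3 and AML 1, 2 and 3. Changed genes numbered 119 with DESeq2 and 293 without the low-count filter. Mmp15, Tgtp2 and Stat2 were lost with the replicate block (edgeR adjusted p = 0.0509, 0.081 and 0.081), Hspa1a, Col14a1 and Tgtp2 with equal cells per library (0.0553, 0.0813 and 0.329), and Tgtp2 with free RNA subtracted (0.0504).

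**Figure D3:**
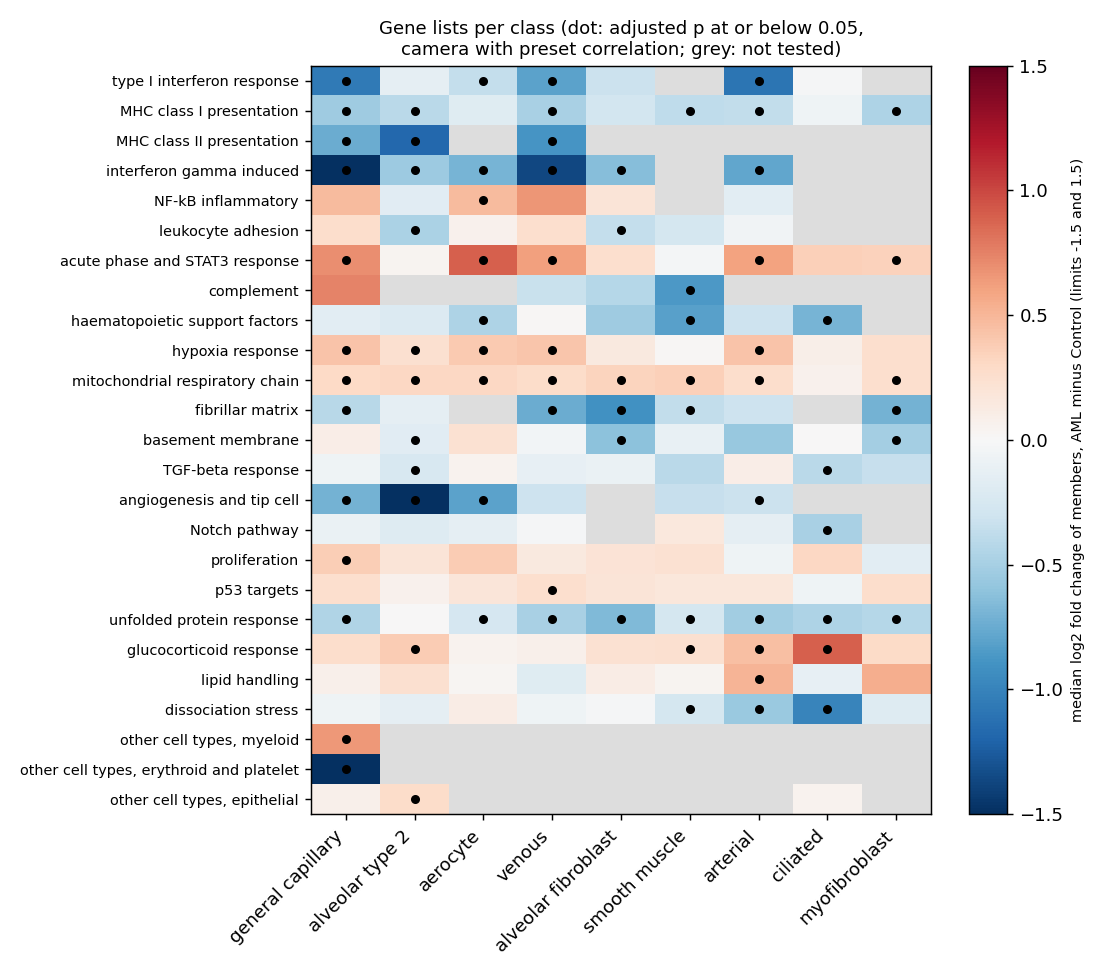
Median log2 fold change (colour) of the measured members of each gene list (rows) in each of 9 cell classes (columns), AML minus Control, for lists called in at least 1 class. A dot marks a camera adjusted p at or below 0.05 with the preset correlation of 0.01, which 80 of 174 pairs of list and class reach and 0 keep with an estimated correlation. The highest of the other splits of the libraries into 3 and 3 gave 60 such calls.

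Alveolar fibroblasts, which support the alveolar wall, had lower Col3a1, Mmp2 and Col15a1 and higher Lox, a collagen crosslinking enzyme, in AML-infiltrated lungs. Col3a1 (chromosome 1, 45311538 to 45349706) fell from 1465 ± 79.3 to 245 ± 155 CPM (SD, n = 3 each; log2 change -2.58 ± 0.42 SE, edgeR adjusted p = 0.00536; 0.161 without Control 1), and Lox (chromosome 18, 52516067 to 52529867) rose from 362 ± 126 to 1643 ± 843 CPM (log2 change 2.18 ± 0.35 SE, edgeR adjusted p = 0.00221). Of 19 measured fibrillar matrix genes, 9 fell and 1 rose. In this list, 11 fell and 1 rose adjusted over the list alone (camera adjusted p = 5.51e-09; adjusted p = 0.425 with an estimated correlation). Mmp2, a gelatinase, fell 4.15-fold and Col1a1 fell 3.27-fold (edgeR adjusted p = 0.104 without Control 1). Of 12 basement membrane genes, Col15a1 fell 12.7-fold and Hspg2 fell. In this list, 7 fell adjusted over the list alone (camera adjusted p = 0.000526; adjusted p = 0.457 with an estimated correlation). Of 15 genes of the unfolded protein response, Calr fell. In this list, 6 fell adjusted over the list alone (camera adjusted p = 6.96e-05; adjusted p = 0.425 with an estimated correlation). Of 11 haematopoietic support factors, 2 rose and 3 fell, and the list was not called (camera adjusted p = 0.0791; adjusted p = 0.425 with an estimated correlation). The growth factor gene Igf1 fell 9.74-fold, the chemokine gene Cxcl12 fell 2.46-fold and Wnt5a rose 2.97-fold. Of 12 lipid handling genes, 3 rose and 1 fell, and the list was not called (camera adjusted p = 0.522; adjusted p = 0.646 with an estimated correlation). The triglyceride-synthesis gene Dgat2 rose 5.53-fold, the lipase gene Pnpla2 rose 3.43-fold and Lpl fell 2.81-fold; with doublets kept, the log2 change of Lpl was -0.02 (edgeR adjusted p = 0.992; 0.483 with the automatic Scrublet threshold). Cd34 fell 3.13-fold and Cd74 went from 50.7 ± 33.0 to 3.94 ± 3.07 CPM, while endothelial markers summed to 402 ± 325 CPM in the Controls and 56.3 ± 18.8 CPM in the AML libraries of this class. Haematopoietic markers summed to 8.9 ± 5.9 CPM in the Controls and 2.2 ± 2.0 CPM in the AML libraries, without overlap.

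Of 6292 genes tested in alveolar fibroblasts, 236 passed (87 higher, 149 lower; 1053 at an unadjusted p below 0.05), 99.6% of them with AML and Control values apart, against 21.5% of the tested genes and 10% by chance. The count was 88 without Control 3, 104 without AML 2, 153 without AML 3, 100 with doublets kept, 132 with equal cells per library and 559 without the low-count filter. With doublets kept 10 of the 29 named genes lost their call and 6 were not tested. Of the 29 named genes that passed, 20, 25, 20, 26, 21 and 19 still did without Control 1, 2 and 3 and AML 1, 2 and 3. Lox, Mmp2, Col15a1, Igf1, Wnt5a, Lpl and Cd34 were kept each time, while Cxcl12 was lost without Control 1 and 3 and AML 2 and 3 (edgeR adjusted p = 0.0541, 0.0622, 0.107 and 0.0683), and with doublets kept (0.532). Hspg2 was lost with DESeq2 (DESeq2 adjusted p = 0.269), and with the replicate block, doublets kept and equal cells per library (edgeR adjusted p = 0.0878, 0.158 and 0.1).

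Myofibroblasts of the alveolar ducts had lower Col6a3 and higher Ms4a4d and Sox4 in AML-infiltrated lungs, and higher values of 4 members of the hypoxia list, which was not called as a list in this class. Ms4a4d, a member of a tetraspan membrane protein family (chromosome 19, 11536801 to 11558467), rose from 21.1 ± 13.9 to 205 ± 69.8 CPM (SD, n = 3 each; log2 change 3.26 ± 0.45 SE, edgeR adjusted p = 0.00141), and the transcription factor gene Sox4 rose 4.65-fold. Of 18 fibrillar matrix genes, 5 fell. In this list, 9 fell adjusted over the list alone (camera adjusted p = 8.8e-07; adjusted p = 0.425 with an estimated correlation); Col3a1 fell 5.41-fold, Col6a3 fell 3.54-fold and Col1a1 fell 2.96-fold. The hypoxia list members Adm, which encodes adrenomedullin, Higd1a, Angptl4 and Bnip3 rose 4.22-fold, 3.18-fold, 2.84-fold and 2.45-fold. Endothelial markers summed to 1282.8, 69.4 and 430.7 CPM in Control 1, 2 and 3 of this class and to 71.1, 30.6 and 39.6 CPM in AML 1, 2 and 3. In this class 52 of 3664 genes passed (25 higher, 27 lower; 553 at an unadjusted p below 0.05), all with AML and Control values apart, against 19.8% of the tested genes and 10% by chance. The count was 94 without Control 2, 25 without Control 3, 106 without AML 1, 9 without AML 2 and 28 without AML 3. Of 19 named genes, 11, 15, 10, 17, 6 and 11 were kept without Control 1, 2 and 3 and AML 1, 2 and 3, with Ms4a4d and Sox4 each time. Changed genes numbered 185 without the low-count filter, 12 with doublets kept, 111 with the automatic Scrublet threshold and 27 with equal cells per library. With doublets kept 11 genes were higher and 1 was lower, and 13 of the 19 named genes lost their call. Among these were Col3a1, Col1a1, Higd1a, Angptl4 and Bnip3 (edgeR adjusted p = 0.0962, 0.0645, 0.0645, 0.0527 and 0.0645), while Col6a3 was kept. With equal cells per library Col3a1, Angptl4 and Bnip3 were lost (edgeR adjusted p = 0.106, 0.0898 and 0.0866). Without AML 2, 8 genes were higher and 1 was lower.

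Smooth muscle cells raised Fabp4, a fatty acid carrier, 4.28-fold from 220.2 ± 129 to 952 ± 155 CPM (SD, n = 3 each; log2 change 2.10 ± 0.34 SE, edgeR adjusted p = 0.00149). The placental growth factor gene Pgf (chromosome 12, 85166635 to 85177790) rose 4.78-fold and the metallothionein gene Mt1 rose 3.48-fold, and the chaperone gene Hspa1b fell 6.91-fold. Col3a1 fell 2.89-fold, and of 18 fibrillar matrix genes it was the 1 that fell, over all genes and adjusted over the list alone (camera adjusted p = 6.17e-05; adjusted p = 0.517 with an estimated correlation; 0.0579 without AML 1). Of 7 haematopoietic support factors, Csf1, the macrophage growth factor, fell 3.12-fold. In this list, 3 fell adjusted over the list alone (camera adjusted p = 0.00282; adjusted p = 0.425 with an estimated correlation). Of 6 complement genes, 0 passed edgeR (3 at an unadjusted p below 0.05, 0 with DESeq2). In this list, 3 fell adjusted over the list alone (camera adjusted p = 0.00146; adjusted p = 0.425 with an estimated correlation). Cdh5, an endothelial junction gene, went from 71.2 ± 13.7 to 4.56 ± 2.19 CPM, and endothelial markers summed to 287 ± 108 CPM in the Controls and 80.4 ± 61.1 CPM in the AML libraries of this class. Epithelial markers summed to 2.4 ± 2.1 CPM in the Controls and 11.6 ± 9.6 CPM in the AML libraries, without overlap, with 22.5 CPM in AML 1. With doublets kept, the log2 change of Cdh5 was -0.66 in place of -3.93. In all, 46 of 5481 genes passed (17 higher, 29 lower; 595 at an unadjusted p below 0.05), all with AML and Control values apart, against 16.4% of the tested genes and 10% by chance. The count was 12 without Control 1, 27 without Control 2, 24 without Control 3 and 74 without AML 1. Of 18 named genes, 6, 12, 11, 16, 17 and 10 were kept without Control 1, 2 and 3 and AML 1, 2 and 3, with Fabp4 and Hspa1b each time. Changed genes numbered 108 without the low-count filter, 23 with doublets kept, 24 with the automatic Scrublet threshold and 7 at the lower clustering resolution. At that resolution 14 of the 18 named genes lost their call, among them Pgf, Mt1, Col3a1 and Csf1 (edgeR adjusted p = 0.0543, 0.0901, 0.0725 and 0.468), and 8 moved by over 1.5 times. With doublets kept 10 lost it, Pgf and Cdh5 among them (edgeR adjusted p = 0.0611 and 0.856), as they did with the automatic threshold (0.0566 and 0.832), and Csf1 lost it with DESeq2 (DESeq2 adjusted p = 0.265).

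Arterial endothelial cells raised the enzyme and the carrier that clear triglycerides from blood. Lpl, lipoprotein lipase (chromosome 8, 68880491 to 68907448), rose from 106 ± 9.63 to 804 ± 185 CPM (SD, n = 3 each; log2 change 2.92 ± 0.27 SE, edgeR adjusted p = 2.97e-05), and Gpihbp1, which anchors it to the capillary wall and is a naming marker of general capillary cells, rose 3.88-fold. With the lower clustering resolution the log2 change of Lpl was 1.69 and that of Gpihbp1 1.16. Of 10 lipid handling genes, these 2 rose. In this list, 4 rose adjusted over the list alone (camera adjusted p = 0.000526; adjusted p = 0.425 with an estimated correlation). Of 10 type I interferon genes, Xaf1 fell. In this list, 7 fell adjusted over the list alone (camera adjusted p = 3.3e-06; adjusted p = 0.425 with an estimated correlation). Of 20 dissociation stress genes, Hspa1a and Hspa1b fell. In this list, 6 fell and 1 rose adjusted over the list alone (camera adjusted p = 3.12e-05; adjusted p = 0.433 with an estimated correlation). The calcineurin regulator gene Rcan1 fell 5.39-fold and Sox4 fell 4.49-fold (edgeR adjusted p = 0.241 with equal cells per library). In this class 27 of 5772 genes passed (12 higher, 15 lower; 708 at an unadjusted p below 0.05), all with AML and Control values apart, against 18.4% of the tested genes and 10% by chance. The count was 15 without Control 3, 130 without AML 1, 3 without AML 2 and 4 without AML 3. Of 15 named genes, 10, 12, 9, 14, 3 and 4 were kept without Control 1, 2 and 3 and AML 1, 2 and 3, with Lpl and Gpihbp1 each time. Changed genes numbered 62 with DESeq2, 192 without the low-count filter, 47 with doublets kept, 58 at the lower clustering resolution and 59 with the automatic Scrublet threshold.

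Ciliated epithelial cells had lower Dnajb1 and Hspa1b and higher Clic3 and Cbr3 in AML-infiltrated lungs. Dnajb1, a partner of HSP70 (chromosome 8, 83608193 to 83612653), fell from 231 ± 36.2 to 44.0 ± 10.9 CPM (SD, n = 3 each; log2 change -2.38 ± 0.25 SE, edgeR adjusted p = 3.95e-09). Of 20 dissociation stress genes, 3 fell, all chaperone genes (Dnajb1, Hspa1b and Hspb1). In this list, 6 fell and 1 rose adjusted over the list alone (camera adjusted p = 7.72e-18; adjusted p = 0.425 with an estimated correlation). The chloride channel gene Clic3 rose 2.92-fold, the carbonyl reductase gene Cbr3 rose 2.93-fold, the aldo-keto reductase gene Akr1b8 rose 3.38-fold and Gsta3 rose 3.54-fold. Of 7 Notch pathway genes, 0 passed edgeR (3 at an unadjusted p below 0.05, 0 with DESeq2). In this list, 3 fell adjusted over the list alone (camera adjusted p = 0.0033; adjusted p = 0.425 with an estimated correlation). Of 8 TGF-beta response genes, the transcription regulator gene Id2 fell 1.99-fold. In this list, 1 fell adjusted over the list alone (camera adjusted p = 0.0025; adjusted p = 0.425 with an estimated correlation). Kitl, the stem cell factor, fell 3.57-fold, but with doublets kept its log2 change was -0.26 (edgeR adjusted p = 0.879). Hspb1 was lost with doublets kept or the automatic Scrublet threshold (edgeR adjusted p = 0.211 and 0.458), as was Gsta3 (0.0509 and 0.0573), and Akr1b8 was lost with the automatic threshold (0.134). Id2 was lost with DESeq2 (DESeq2 adjusted p = 0.123) and with equal cells per library (edgeR adjusted p = 0.505), as was Kitl with equal cells (0.113). In this class 42 of 6823 genes passed (18 higher, 24 lower; 627 at an unadjusted p below 0.05), all with AML and Control values apart, against 14.6% of the tested genes and 10% by chance. The count was 166 without AML 1 and 22 without AML 3. Of 13 named genes, 9, 12, 12, 12, 12 and 9 were kept without Control 1, 2 and 3 and AML 1, 2 and 3, with Dnajb1 and Clic3 each time. Changed genes numbered 84 without the low-count filter and 121 with doublets kept.

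Across classes, 911 genes passed in at least 1 class, 719 of them in 1 class and 12 in at least 5. The genes shared most widely were Cirbp and Rbm3 and a set of chaperone genes. Cirbp, induced by cold, rose in 8 of the 9 classes, and Rbm3, another cold-inducible RNA-binding protein, rose in 7. The chaperone genes Hspa1a, Hspa1b, Dnaja1 and Serpinh1 fell in 7 classes each, Hsph1, Ahsa2 and Chordc1 fell in 5, and P4ha1, a collagen hydroxylase, fell in 5. Ly6c1, Ucp2, Gsta3 and Hmgb2 rose in 4 classes each, while Lpl rose in 3 and fell in 1. In smooth muscle cells Cirbp went from 50.9 ± 13.5 to 212.6 ± 92.1 CPM (SD, n = 3 each; log2 change 2.01 ± 0.32 SE, edgeR adjusted p = 0.0014), a call lost without Control 1 (edgeR adjusted p = 0.0582). Without AML 3 the call of Cirbp was lost in general capillary, alveolar type 2, venous and arterial cells (edgeR adjusted p = 0.0897, 0.204, 0.152 and 0.0941).

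**Figure D4:**
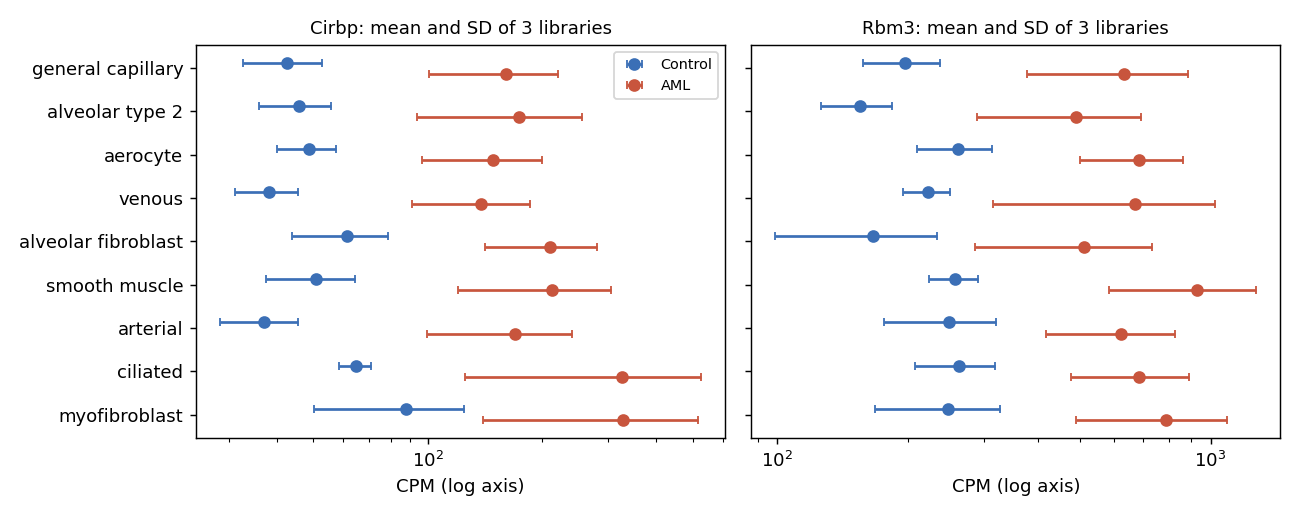
Mean and SD of 3 libraries of the CPM (log axes) of Cirbp and Rbm3 in each of 9 classes, Controls in blue and AML libraries in red. Cirbp goes from 64.7 to 326.5 CPM in ciliated cells, where it did not pass (edgeR adjusted p = 0.376), and from 42.7 to 160.8 CPM in general capillary cells, where it did.

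Some lists were called in most classes with small shifts. The unfolded protein response was lower in 8 of 9 classes (lowest camera adjusted p = 2.04e-06, in ciliated cells; lowest adjusted p = 0.425 with an estimated correlation), with 1 member past edgeR in aerocytes (Hyou1) and 1 in alveolar fibroblasts. Hyou1 was lost with DESeq2 (DESeq2 adjusted p = 0.12) and with free RNA subtracted (edgeR adjusted p = 0.0537). The mitochondrial respiratory chain was higher in 8 classes (lowest camera adjusted p = 4.45e-05; lowest adjusted p = 0.517 with an estimated correlation) with medians of at most 0.36. In these classes 0 of its members passed edgeR or DESeq2. Its call was lost without Control 1 in aerocytes, alveolar fibroblasts, smooth muscle cells and myofibroblasts (camera adjusted p = 0.119, 0.0622, 0.0733 and 0.218). Lists of MHC class I presentation and of interferon gamma induced genes were each lower in 6 classes, and fibrillar matrix in 5. At most 1 member of the MHC class I list passed edgeR in a class where that list was called. Acute phase and hypoxia genes were each higher in 5 classes, and glucocorticoid response genes in 4, with Mt2 and Sult1a1 higher in arterial cells. In all, 80 of 174 pairs of list and class were called, and 0 were called with an estimated correlation (14 at an unadjusted p below 0.05) or with fry (42). Of the other splits of the 6 libraries into 3 and 3, the highest gave 60 list calls. Many calls at the preset correlation can thus arise without the grouping by leukaemia.

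Shares of niche cells were compared among the non-haematopoietic cells of named clusters of each library, which leaves out the unnamed clusters. Aerocytes made up 11.2% ± 1.80 of these cells in the Controls and 6.59% ± 1.40 in the AML libraries (SD, n = 3 each), alveolar fibroblasts 2.36% ± 0.52 and 6.09% ± 3.43, and myofibroblasts 1.33% ± 0.14 and 2.30% ± 0.30. In these 3 classes no AML library overlapped a Control, with p = 0.1 in the exact two-sided permutation test, the smallest p that 3 libraries against 3 allow, and 0.467 after adjustment over 14 classes. General capillary cells held 60.6% ± 5.39 and 64.8% ± 2.03 (exact permutation p = 0.3), and alveolar type 2 cells 10.4% ± 8.02 and 6.96% ± 0.82 (exact permutation p = 0.9), with 19.7% in Control 1. In both of these classes the difference turned its direction at the lower clustering resolution. With the unnamed clusters in the base, as planned but added only after the data were seen, general capillary cells held 55.1% ± 5.63 and 63.7% ± 1.95 and arterial cells 1.57% ± 0.18 and 2.30% ± 0.54, both without overlap (exact permutation p = 0.1, adjusted p = 0.28). Aerocytes then held 10.2% ± 1.95 and 6.48% ± 1.38, and aerocytes, alveolar fibroblasts and myofibroblasts stayed without overlap (exact permutation p = 0.1, adjusted p = 0.28). Unnamed cells count in this base but in no class, so they lower every share of a library. Cluster 13 held 13.56% of Control 3 cells, 0.06% of Control 1 and 0% elsewhere. Cluster 14, a mean 3.49% of Control and 0.6% of AML cells, had general capillary as its nearest class, with 7 markers detected. It stayed unnamed because genes of another lineage led it. The gap between the groups for general capillary cells may depend on leaving it out. Sorting, the filters and the lower UMIs per cell of the AML libraries could all set these shares.

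**Figure D5:**
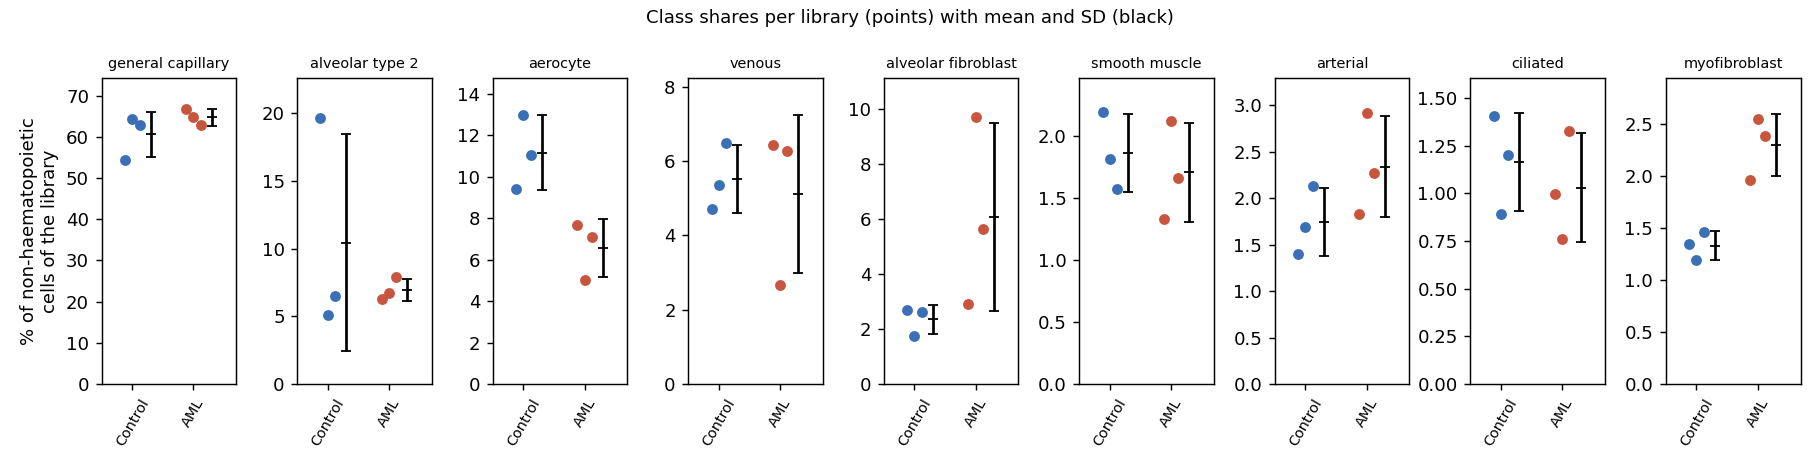
Share of each of 9 classes among the non-haematopoietic cells of named clusters of each library (vertical axes in percent, each starting at 0), with points for libraries and black marks for the mean and SD of 3. Aerocytes lie between 9.40% and 13.01% in the Controls and between 5.01% and 7.68% in the AML libraries.

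Whether the change with leukaemia differed between general capillary cells and alveolar type 2 cells was tested within libraries. Of 9184 genes, 1 differed past the threshold (limma, 1397 at an unadjusted p below 0.05): Cpt1b, which imports fatty acids into mitochondria (ENSMUSG00000078937, chromosome 15, 89416405 to 89425863). Its log2 change was -1.18 in general capillary cells (2.12 ± 0.634 to 0.932 ± 0.436 CPM) and 2.43 in alveolar type 2 cells (1.05 ± 0.491 to 5.98 ± 1.64 CPM; SD, n = 3 each), with a difference of -3.05 ± 0.23 SE (limma adjusted p = 0.0124). The changes per class are edgeR estimates and the difference is from limma with a prior count of 2, so they do not subtract exactly. The CPM values are low. The call was lost without Control 1, Control 2, Control 3 or AML 3 (limma adjusted p = 0.142, 0.0827, 0.0668 and 0.133) and without the low-count filter (limma adjusted p = 0.194). Without Control 2 another gene passed in its place, without AML 1 the count was 77, and without AML 2 it was 2. It was 0 without Control 1, Control 3, AML 3 or the filter (limma, 1064, 1115, 1232 and 1965 at an unadjusted p below 0.05). Bcam, a laminin receptor, came next with a difference of 1.31 ± 0.16 SE (limma adjusted p = 0.0703), which did not pass.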

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

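The tests of added leukaemia cell RNA, of lymphocytes, of dissociation, of immune cell RNA, and of UMIs per cell beyond the type I interferon list in general capillary cells were chosen only after the results were seen. Those of a heat shock programme and of UMIs per cell for that list were written before they were run, but for patterns already seen.

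The haematopoietic cells enter no comparison before this section. Some groups of them stood higher in every AML library than in every Control. Clusters found almost only in AML libraries made up 18.95% of AML cells, against 0.13% in the Controls. They consist of erythroid-like cells (18.59%, against 0.13%) and mast or basophil-like cells (0.36%, against 0%), so these are not separate rises. B lymphocyte-like cells made up 1.6% against 0.98%. Leukaemia cells had been added to the AML libraries at 20%. In B lymphocyte-like cells Cirbp stood at 352.5 CPM (Control 141.2) and Rbm3 at 809.8 CPM (Control 327.9). In T or NK lymphocyte-like cells they stood at 217.7 CPM (Control 85.1) and 848.1 CPM (Control 300.9). The smallest library held 8 B cells and 18 T or NK cells.

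Cirbp and Rbm3 were higher and heat shock genes lower in the AML libraries across most classes. RNA from the added leukaemia cells is argued against: their CPM of these genes was at most 4.275 times the rise in a class, where a small share of foreign RNA would need at least 10 times. The prediction for a change of the heat shock programme was met. The median of the measured members of 11 chaperone genes outside the lists (11 in most classes, 9 in arterial, 10 in ciliated and myofibroblast cells) lay below -0.3 in 8 of 9 classes (median over classes -0.488). These are genes of the same kind in the same libraries. The result therefore shows that the fall reached further chaperone genes, and it decides no cause. Lymphocyte-like cells showed the same directions without overlap in 8 of 8 comparisons of Cirbp, Rbm3, Hsph1 and Hspa8, but that test decides nothing, since it was chosen after the rise of Cirbp and Rbm3 there was seen and handling would give the same. Dnaja1, outside that test, fell without overlap in B cells but overlapped in T or NK cells, at 586.9 CPM in AML 3 and 561.4 CPM in Control 1. Dissociation time or stress cannot be told apart from a change of the heat shock programme: immediate early genes had a median of 0.008 against -0.785 for the heat shock members, but their members spread by 0.585. Handling temperature or time may differ between the groups as well as leukaemia itself, and the labels give neither, so the biological explanation stays open and untested.

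Lists of interferon and MHC class II genes were called lower in the AML libraries in general capillary and venous cells with the preset correlation. None of these calls held with an estimated correlation (lowest adjusted p = 0.425), and 0 of 7 class II members passed in either class (0 in general capillary and 1 in venous cells at an unadjusted p below 0.05). Fewer UMIs per cell are argued against for the type I interferon list in general capillary cells alone: among cells of 2000 to 6000 UMIs (medians 4063 in the Controls and 3639 in the AML libraries) its median log2 difference was -1.059, against -1.069 over all cells. For the other lists and for venous cells they cannot be told apart from a change with leukaemia. In general capillary cells the difference was -1.164 (-1.689 over all cells) for the interferon gamma list and -1.175 (-1.289) for class II, and their ratio fell as low as 0.603 and 0.745 when libraries were left out, below the bound of 0.8. In venous cells it was 0.425 (-0.817) for type I interferon, -1.064 (-1.49) for interferon gamma and -0.53 (-1.403) for class II, with 7 cells in the smallest library.

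RNA of immune cells in the Controls is argued against, since it gives 0.035% of the UMIs of the median member in general capillary cells and 0.05% in venous cells, where under 10% had been set as the bound. An effect of leukaemia on interferon signalling may remain for the type I list in general capillary cells, as a hypothesis found and tested on these data. The test of UMIs per cell did not hold the clusters of this class fixed. A shift in their mix therefore cannot be told apart from such an effect. A difference in the animals or their housing was not tested.

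Cpt1b was singled out because its change differed between general capillary and alveolar type 2 cells, with a log2 difference of -3.046 (limma adjusted p = 0.0124).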

How the results depend on the processing

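The automatic Scrublet threshold, the leaving out of clusters mostly of 1 library and the base of shares with unnamed clusters were chosen after the data were seen. The doublet rule of the main results was set after the calls of that threshold were seen. Of 234 named pairs of gene and class that passed, 186 lost the call without at least 1 library and 86 in at least 1 other alternative. Of 80 list calls, 0 held with camera and an estimated correlation (14 at an unadjusted p below 0.05) and 0 with fry (42), and 49 held without members higher in haematopoietic cells, where 17 did not, the rest were not tested and 50 calls were made in all, and 0 lists turned their direction. The causes were not tested.

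Counts of changed genes moved by over 1.5 times as follows. With DESeq2 they were 881 in general capillary, 266 in alveolar type 2, 119 in venous and 62 in arterial cells. Without the low-count filter they were 845 in general capillary, 794 in alveolar type 2, 602 in aerocyte, 293 in venous, 559 in alveolar fibroblast, 108 in smooth muscle, 192 in arterial, 84 in ciliated and 185 in myofibroblast cells. With doublets kept they were 100 in alveolar fibroblasts, 23 in smooth muscle, 47 in arterial, 121 in ciliated and 12 in myofibroblast cells. At Leiden resolution 0.5 they were 460 in alveolar type 2, 7 in smooth muscle and 58 in arterial cells. With the automatic Scrublet threshold they were 80 in alveolar type 2, 24 in smooth muscle, 59 in arterial and 111 in myofibroblast cells. They were 454 in alveolar type 2 cells without clusters mostly of 1 library, and with equal cells 132 in alveolar fibroblasts and 27 in myofibroblasts. The difference between classes had 0 genes without the filter. DESeq2 size factors, the stricter filter and subtraction of free RNA moved no count by over 1.5 times. That subtraction took only the RNA of each library's haematopoietic cells, at most 2.58% of the UMIs of a class (aerocytes of AML 2). Free RNA of endothelial, mesenchymal or epithelial cells was not subtracted, so its part was not tested.

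With each library left out in turn, counts ranged from 0 to 1289 in general capillary, 0 to 267 in alveolar type 2, 68 to 373 in aerocyte, 0 to 322 in venous, 88 to 295 in alveolar fibroblast, 12 to 74 in smooth muscle, 3 to 130 in arterial, 22 to 166 in ciliated and 9 to 106 in myofibroblast cells. List calls ranged from 65 to 86 and the difference from 0 to 77 genes.

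The correlations gave no clear sign that the replicate numbers pair the libraries. Same-numbered libraries correlated at -0.176 to 0.14, above 0.1 in 1 of 27 pairs, and in 0 classes did every library correlate best with its own number. Taken around means of 3 libraries, these values cannot exclude a pairing. The replicate block gave 456 genes in alveolar type 2, 83 in arterial, 66 in ciliated and 157 in myofibroblast cells, and moved the other counts by under 1.5 times.

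Differences of class shares (AML minus Control, percentage points) turned for general capillary cells at Leiden resolution 0.5 (-0.462), venous cells with doublets kept (0.374) or the automatic threshold (0.239), alveolar type 2 cells at Leiden resolution 0.5 (0.582) or without clusters mostly of 1 library (0.566), and alveolar type 1 cells with the stricter filter (0.014). With unnamed clusters in the base they turned for venous (0.064) and alveolar type 1 cells (0.031), and that of general capillary cells was 8.62, without overlap of the groups. That base counts cluster 14, nearest to general capillary cells by its markers, in no class. With libraries left out they ranged from 1.926 to 5.33 for alveolar fibroblasts (3.738 with all), 1.085 to 6.073 for general capillary, -1.048 to 0.831 for venous, -0.364 to 0.034 for smooth muscle, -6.129 to 1.14 for alveolar type 2 and -0.181 to 0.143 for alveolar type 1 cells.

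Log2 changes turned for Id1 in alveolar type 2 cells with doublets kept (0.06), for Id3 in ciliated cells with equal cells (0.102), and for Lyve1 in smooth muscle cells with doublets kept (1.221), at Leiden resolution 0.5 (0.702) and with the automatic threshold (0.995).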

Other observations

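The tests of splits were planned, and no value here rests on a test chosen only after the result was seen. Some genes outside the lists changed in several classes, and they were picked after their values were seen. Gsta3, a glutathione transferase, rose in 4 of the 4 classes in which it was tested, and Tiparp rose in 3 classes and fell in 1. Fmo2, a flavin monooxygenase, rose in 3 classes and fell in 1. Cyp1a1, a cytochrome P450 induced by the aryl hydrocarbon receptor, stood at 48.3 CPM in the Control and 0.481 CPM in the AML libraries in aerocytes (edgeR adjusted p = 0.000745), but its edgeR adjusted p was 0.0612 with doublets kept and 0.0559 with the automatic Scrublet threshold. Ccnd2, a cyclin, fell in 4 of 8 classes.

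AML 1 was the AML library nearest to the Controls for 77.9% of the changed genes of general capillary cells, 75.0% in alveolar type 2, 75.8% in aerocyte, 66.0% in venous, 50.4% in alveolar fibroblast, 52.2% in smooth muscle, 77.8% in arterial, 81.0% in ciliated and 67.3% in myofibroblast cells. Haemoglobin Hbb-bs stood at 1224 CPM in general capillary cells and 1375 CPM in alveolar type 2 cells of Control 3, and at 857 CPM in aerocytes of Control 1.

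The 6 libraries make 10 splits into 3 and 3, so the share of splits with a result as large is never under 0.1. In each case 1 of the 10 splits, the real split, reached its value. The real count and the highest of the other splits were 312 and 0 genes in general capillary, 148 and 1 in alveolar type 2, 302 and 0 in aerocyte, 47 and 1 in venous, 236 and 1 in alveolar fibroblast, 46 and 2 in smooth muscle, 27 and 0 in arterial, 42 and 6 in ciliated and 52 and 1 in myofibroblast cells. They were 80 and 60 for list calls and 1 and 0 for the difference between classes.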
